A study of Mus musculus with 16 samples.

How the data were processed

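The series holds single-cell RNA libraries (10x Genomics) of mouse liver cells, sorted as described per the labels' protocols. The deposited values are counts: whole-number UMI counts per gene and cell barcode, 1 matrix per library, made with Cell Ranger on the mm10 build per the submitters' processing notes (its version is not given in the sources used here). Each matrix holds 28002 features, of which 27998 are genes and 4 are added sequences (Cre, eYFP and their antisense). The deposited matrices hold barcodes already called as cells, since the lowest total per barcode was 1080 to 2849 UMIs in the time course and 500 to 705 in the Smad4 part. No normalisation had been applied by the authors to the deposited counts, as judged from the values. Matrices of 15 libraries were used. Time-course matrices were assigned to samples by title. A YFP+ library of week 3 was not analysed here.

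Barcodes with under 250 genes or under 500 UMIs (3367), barcodes called as doublets (11641, or 8.4%) and barcodes with over 30% mitochondrial UMIs (3193) were left out. Doublets were called by the share of simulated doublets among nearest neighbours, at an expected rate of 0.8% per 1000 barcodes. The score was tested on 1500 simulated cells and recovered 100% of 100 doublets between types. The Smad4 libraries and the time-course libraries were clustered apart, each over 2000 variable genes, 30 principal components and 15 neighbours with the Leiden algorithm at resolution 1. A cluster was named from marker lists fixed before the data were examined, by the mean log2 ratio of its markers over all clusters after adding 10 CPM, with a margin of 0.5, a score of 3 for other types and at least 3 markers. A cluster whose 10 leading genes held more markers of another type than of its own was kept apart in an alternative.

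UMI counts were summed per library over all kept cells or over the cells of a class (libraries with at least 20 such cells) and tested with edgeR's quasi-likelihood test, after filtering on low counts and scaling by the trimmed mean of M-values (TMM). The 8 Smad4 libraries entered 1 fit with 1 coefficient per group, for mutant against control in each sort and for the interaction. The 10 libraries of weeks 2, 4 and 6 and of the Smad4 controls, where both sorts were available, entered a fit of sort with week or control group as a stratum. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Mean CPM values beside these tests are TMM-scaled, while those of Smad4, of Hamp and of Id1 plus Id3 per cell class, and those of the time course, are plain CPM. The 12 marker and 20 programme lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, with adjustment over the lists of a comparison. Adjustment over the list alone used the p-values of its members. Fry, which asks whether a list's members moved on balance in 1 direction, gave an adjusted p of 0.0193 for BMP targets in all YFP+ cells, 0.0014 in hepatocyte clusters and 0.0434 in biliary clusters. It was run on every list and comparison, and its other values are not given here, so these do not set BMP targets apart from other lists.

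Named genes were Smad4; per direction, the 8 called genes with the largest fold change among those with a mean of at least 20 CPM and the same sign in every replicate number or stratum, leaving out mitochondrial, ribosomal and predicted genes; up to 4 called members per list; and, where under 5 genes were called, the 3 most expressed TGF-beta targets, hepatocyte markers and biliary markers. In the untested time course they were the 8 genes per direction with the largest ratio of week 6 to week 2 among those with at least 100 CPM in 1 library and every later week on the same side of week 2, and up to 3 of the most expressed members per list. Hamp and Id1 plus Id3 within hepatocyte clusters, and the transcripts looked up in stellate and portal fibroblast clusters, were chosen after their values in other comparisons were seen. Coordinates come from the GENCODE M21 annotation (mm10), in which 281 of 282 named genes were found.

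Shares of cells were compared with exact two-sided permutation tests. The time course, with 1 library per week and sort, was not tested. A fit with added terms for week and sort, in which each sort would serve as a replicate of the other, was not made. List medians were set against 10000 random lists matched on mean expression. Intervals are 95% exact binomial or Poisson intervals and cover counting error only. Shares of cells with a UMI were also given after thinning each cell to 1000 UMIs.

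On simulated counts with changes in 200 genes, the YFP+ genotype comparison recovered 8% of 2-fold and 62% of 4-fold changes among 15767 genes (100 genes each), with 4.1% of calls false, and the sort comparison 59% and 92% among 14735 genes, with 8.5% of calls false. Replicates differed by more than counting noise in each group (chi-square per degree of freedom 327 to 687). Another scaling moved the median of all genes by 0.04 or less on the log2 scale.

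Alternatives changed 1 choice at a time: size factors of DESeq2, the DESeq2 test with its own size factors (so that test and scaling changed together), no filter on low counts, a mitochondrial limit of 15% or none, at least 1000 UMIs, doublets kept, resolutions of 0.5 and 2, a replicate block, only the 4 libraries of a sort, mutant libraries added to the fit of sort, and each library or stratum left out. Chosen after the data were seen were: only barcodes with at least 1% mitochondrial UMIs, biliary clusters parted by the leading-gene check or by eYFP, shares over epithelial clusters alone, and a clustering without genes that edgeR or DESeq2 called by genotype within a class. Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9) and R 4.3.3 (edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0) were used.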

Results

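Single-cell RNA sequencing (10x Genomics) was used to profile liver cells of male mice fed chow with 0.1% DDC, a compound that disturbs porphyrin metabolism and injures the bile ducts. The mice carried a YFP reporter and had received AAV8-TBG-Cre, a virus that expresses Cre recombinase in hepatocytes, so that hepatocytes and cells derived from them make YFP. The study asks how hepatocytes take on biliary features during this injury and what Smad4, a shared mediator of TGF-beta and BMP signalling, contributes. Endothelial and immune cells were removed by sorting on surface markers. The remaining live cells were profiled either without a further gate (bulk, YFP-positive and YFP-negative cells together) or after a gate for YFP (YFP+). The time course held 1 bulk library from each of weeks 2, 3, 4 and 6 of diet and 1 YFP+ library from each of weeks 2, 4 and 6. The Smad4 part, at week 4, held 2 bulk and 2 YFP+ libraries of mice with 1 floxed Smad4 allele (controls) and of mice with both alleles floxed (mutants). The labels do not say whether replicates came from separate mice, so that p-values measure the spread between these libraries.

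Libraries differed in depth. In the time course the bulk libraries of weeks 2, 3, 4 and 6 held 27848368, 27461243, 56089865 and 39612076 UMIs (unique molecular identifiers, the counted transcript molecules). The YFP+ libraries of weeks 2, 4 and 6 held 12502032, 21126693 and 34342543 UMIs. In the Smad4 part, replicates 1 and 2 held 67452080 and 90630538 UMIs in bulk controls and 91810407 and 93591926 in bulk mutants. They held 102784961 and 110875091 UMIs in YFP+ controls and 89976802 and 89624155 in YFP+ mutants. After filtering, 124382 of 142583 barcodes remained, with a median of 1304 to 15889 UMIs per cell and library. Barcodes with under 1% mitochondrial UMIs made up 66.2% of bulk control replicate 1, 27.8% of bulk mutant replicate 1, 18.1% and 18.7% of the replicate 2 bulk libraries and 1.6% to 8.4% of the YFP+ libraries of the Smad4 part. In the time course they made up 24.4% to 64.8% of each library.

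Clusters fell into hepatocyte-like, biliary-like and smaller mesenchymal, macrophage, endothelial and mesothelial groups. In the Smad4 part, clusters 0, 3, 4, 8, 13 and 14 carried biliary markers such as Spp1, Sox9 and Epcam, clusters 1, 2, 5, 6, 7 and 10 carried hepatocyte markers such as Alb, and clusters 9 and 12 lay between them. Clusters 15 and 18 were stellate-like and cluster 16 portal fibroblast-like. In the time course, clusters 4, 6 and 13 carried biliary markers, and cluster 0, which held 69.5% of the bulk and 74.52% of the YFP+ cells of week 2, met no naming rule. In cluster 8 of the Smad4 part and cluster 6 of the time course, the 10 leading genes held a stellate marker, Rgs5, and no biliary marker. Biliary clusters are therefore given by number, and shares and gene counts are also given without these clusters.

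The reporter parted the biliary clusters. An eYFP UMI was found in 13.4% of cluster 0 cells and in 73.7% to 91.6% of the cells of clusters 3, 4, 8, 13 and 14, here called eYFP-high (a division at 25% made after the data were seen). Stellate-like cells, which should lack the reporter, gave the background. Of these, 13.0% and 8.8% had an eYFP UMI in the bulk control libraries at median depths of 3685.5 and 4594 UMIs, against 18.1% and 27.3% of biliary-cluster cells at 10091 and 9567.5 UMIs. In the YFP+ libraries 88.2% and 86.7% of biliary-cluster cells of controls and 77.0% and 81.8% of mutants had an eYFP UMI, at median depths of 9146.5, 4596.5, 5223 and 3965 UMIs. Thinned to 1000 UMIs per cell, the values were 33.4% and 45.2% against 27.9% and 41.8%, leaving out 6, 48, 165 and 97 shallower cells. For the stellate-like cells of the bulk controls the thinned shares were 4.3% and 2.1%, leaving out 96 and 41 cells, and for their biliary clusters 2.6% and 11.2%, leaving out 5 and 10.

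Smad4, the targeted gene (ENSMUSG00000024515, chromosome 18, 73639009 to 73703780, minus strand, mm10), was lower in mutant cells of hepatocyte origin. Over all cells it stood at 26.6 and 41.4 CPM (UMIs of the gene scaled to a common library total) in YFP+ control replicates 1 and 2, against 18.6 and 10.5 CPM in the YFP+ mutants. In the bulk libraries it stood at 36.3 and 53.5 CPM in controls against 47.3 and 27.2 CPM in mutants. In the time course, where Smad4 was not floxed, it stood at 12, 11.6, 13.2 and 14.5 CPM in the bulk libraries of weeks 2, 3, 4 and 6, and at 15.0, 16.1 and 10.1 CPM in the YFP+ libraries of weeks 2, 4 and 6. The time course and the Smad4 part differ in depth and in the lowest UMI total per barcode, so their levels are not directly comparable. Smad5 also stood lower in the time course (7.9 to 14.1 against 15.6 to 27.6 CPM), while the ranges of Smad1, Smad2 and Smad3 overlapped. Within the hepatocyte clusters of the YFP+ libraries the values were 26.2 ± 5.44 CPM in controls and 6.37 ± 0.354 CPM in mutants (SD, n = 2), and in their eYFP-high biliary clusters 70.2 ± 10.9 and 20.1 ± 1.77 CPM. The biliary cells of cluster 0 in bulk libraries, which are low in eYFP, gave 80.3 ± 5.73 CPM in controls and 71.2 ± 5.3 CPM in mutants, and stellate-like and portal fibroblast-like cells 75.9 ± 1.91 and 66.3 ± 2.69 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Smad4 fell by 1.80 on the log2 scale in the biliary clusters of the YFP+ libraries (SE 0.21, adjusted p = 0.0231). In all cells of these libraries its log2 fold change of −1.58 missed the threshold (SE 0.30, adjusted p = 0.0813). The labels do not say whether the counted tags lie in the deleted part of the gene, so the remaining level does not measure remaining function.

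The comparison of mutant with control YFP+ libraries asks what the loss of Smad4 in hepatocytes and their descendants changed. Id1 and Id3, direct targets of BMP signalling that encode inhibitors of basic helix-loop-helix factors, fell from 161 ± 38.7 to 6.95 ± 2.06 CPM and from 166 ± 15.8 to 5.48 ± 0.917 CPM (SD, n = 2, scaled by trimmed mean of M-values). Prlr, the prolactin receptor, fell from 66.3 ± 15.4 to 16.2 ± 2.53 CPM. Serpina6, which encodes corticosteroid-binding globulin, rose from 18.9 ± 1.29 to 275 ± 58.1 CPM, and Cryab, a small heat shock protein, from 8.45 ± 0.207 to 67.9 ± 11.2 CPM. The proliferation-associated Hmgb2 rose from 33.4 ± 0.618 to 141 ± 46.7 CPM, Cd74, the invariant chain of class II antigen presentation, from 24.95 ± 6.76 to 121 ± 0.354 CPM, and Bex4 from 7.17 ± 1.09 to 48.1 ± 7.92 CPM.

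By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 69 of 16050 genes rose and 4 fell in mutant YFP+ libraries. The log2 fold change was −4.54 for Id1 (SE 0.51, adjusted p = 0.0304), −4.92 for Id3 (SE 0.53, adjusted p = 0.0274), 3.86 for Serpina6 (SE 0.28, adjusted p = 0.0128) and 3.01 for Cryab (SE 0.20, adjusted p = 0.0128), each in the same direction in both replicate numbers. Id1 lies on chromosome 2 (152736251 to 152737410), Id3 on chromosome 4 (136143497 to 136145755) and Serpina6 on chromosome 12 (103646630 to 103657212, mm10). Of 11 measured BMP targets, 3 fell over all genes tested and 9 fell adjusted over the list alone (median log2 fold change −2.94, camera adjusted p = 2.27e-17, adjusted p = 0.0675 with an estimated correlation). Of 15 biliary markers, Cftr rose (2.38 ± 0.579 to 25.5 ± 11.4 CPM), 7 rose adjusted over the list alone, and all 15 had positive fold changes (median 1.14, camera adjusted p = 8.49e-10, adjusted p = 0.533 with an estimated correlation). Of 19 cell cycle genes, Hmgb2 rose and 16 rose adjusted over the list alone (median 2.08, camera adjusted p = 9.63e-20, adjusted p = 0.533 with an estimated correlation). None of the 20 hepatocyte markers passed the test over all genes or adjusted over the list alone, and their median was −0.93 (camera adjusted p = 5.58e-06, adjusted p = 0.533 with an estimated correlation). All 16 drug metabolism genes (median −1.35, camera adjusted p = 2.04e-07) and all 15 acute phase genes (median −1.19, camera adjusted p = 3.32e-07) had negative fold changes, each with an adjusted p = 0.533 with an estimated correlation. Sums over all cells mix the makeup of a library with levels within a class. Hepatocyte clusters held 79.72% and 49.82% of YFP+ control cells and 6.79% and 33.16% of YFP+ mutant cells. Among 23 TGF-beta targets, Itgb6 rose (0.466 ± 0.0119 to 3.12 ± 0.597 CPM), also adjusted over the list alone, and the list did not pass (median 0.00, mean 0.20, camera direction lower, adjusted p = 0.894). The number of called genes rested on single libraries. It was 0 without YFP+ control replicate 1 or without control replicate 2, 4 without mutant replicate 1 and 495 without mutant replicate 2. It was 0 with the 4 YFP+ libraries fitted alone or with YFP+ and bulk counts summed, and 1061 by DESeq2.

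Biliary clusters held a larger share of mutant than of control libraries, a difference set against an exact test that cannot go below 0.05 with these numbers of libraries. They held 15.52% and 24.88% of the cells of YFP+ control replicates 1 and 2, against 74.51% and 52.25% of the YFP+ mutants. In the bulk libraries they held 6.2% and 36.05% of control cells and 49.7% and 55.71% of mutant cells. Much of this bulk difference lay in cluster 0, which is low in eYFP and had Smad4 close to the control level. Cluster 0 held 5.78% and 26.59% of bulk control cells and 38.51% and 28.33% of bulk mutant cells. The mean bulk difference was 31.58 points in all biliary clusters and 14.35 points in eYFP-high ones. The mean difference over both sorts was 37.38 percentage points (exact two-sided permutation test of genotype labels within sort, p = 0.0556, the smallest that 36 arrangements allow), and 43.18 points in the YFP+ libraries alone (6 arrangements, too few for an exact p below 0.05). Without cluster 8 the shares were 3.43% and 3.99% in YFP+ controls, 73.99% and 48.33% in YFP+ mutants, 6.11% and 28.77% in bulk controls and 49.64% and 53.78% in bulk mutants (mean difference 45.86 points, exact p = 0.0556). Different clusters held the class in each group. Cluster 8 held 12.1% and 20.89% of YFP+ control cells and 0.51% and 3.92% of YFP+ mutant cells. Cluster 3 held 47.76% of YFP+ mutant replicate 1, and cluster 4 held 37.46% of YFP+ mutant replicate 2. Hepatocyte clusters held 79.72% and 49.82% of YFP+ control cells and 6.79% and 33.16% of YFP+ mutant cells. Since cluster-defining genes differed by genotype, the cells were clustered again without 734 genes that edgeR or DESeq2 called by genotype within a class. The biliary shares were then 19.5% and 24.66% in YFP+ controls, 84.59% and 47.95% in YFP+ mutants, 6.15% and 35.33% in bulk controls and 51.78% and 53.25% in bulk mutants (mean difference 37.98 points, exact p = 0.0556).

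**Figure D1:**
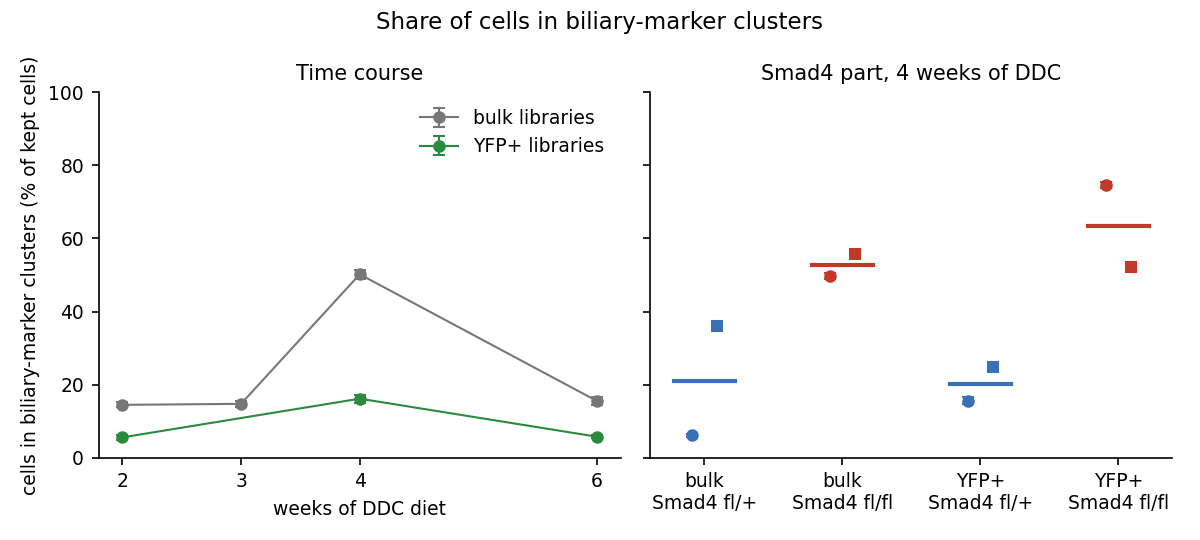
Share of kept cells (percent) in biliary-marker clusters by week of diet (left, 1 library per point) and by sort and genotype in the Smad4 part (right, circles for replicate 1, squares for replicate 2, lines for means), with 95% exact binomial intervals as bars. The YFP+ mutants lie at 74.51% and 52.25%, above the YFP+ controls at 15.52% and 24.88%.

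Within hepatocyte clusters, BMP target genes stood far lower in mutant than in control YFP+ cells. Id1 and Id3 together stood at 219 to 282 CPM in the controls and at 1.97 to 6.67 CPM in the mutants. Hamp, which encodes the iron hormone hepcidin and is induced by BMP signalling, stood at 3010 ± 297 CPM in controls and 18 ± 25.3 CPM in mutants (SD, n = 2). Its close paralog Hamp2 makes the split of reads between the pair uncertain. Of 12 pericentral hepatocyte genes, 11 had positive fold changes (median 1.28), and 1 rose adjusted over the list alone (camera adjusted p = 9.07e-14, adjusted p = 0.144 with an estimated correlation). The general hepatocyte markers had a median of 0.01, with Alb at 0.10, Apoa1 at 0.11 and Apoa2 at 0.13 on the log2 scale.

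Of 11 BMP targets in hepatocyte clusters, 0 passed over all genes and 10 fell adjusted over the list alone (median log2 fold change −3.35, camera adjusted p = 4.4e-67, adjusted p = 0.00171 with an estimated correlation). For cell cycle genes the median was 0.93 (camera adjusted p = 4.42e-11, adjusted p = 0.663 with an estimated correlation) and for acute phase genes, of which 1 fell adjusted over the list alone, −0.41 (camera adjusted p = 5.1e-05, adjusted p = 0.663 with an estimated correlation). The TGF-beta targets had a median of −0.02, with Fn1 at 0.12, Junb at −0.29 and Bhlhe40 at −0.12, and did not pass. Single genes did not pass either: edgeR's quasi-likelihood test called 0 of 12963 genes, with 391 at an unadjusted p under 0.05 and 32 called by DESeq2. The hepatocyte clusters differed between libraries, with cluster 7 holding 69.79% of YFP+ control replicate 1 and cluster 5 holding 43.95% of YFP+ control replicate 2. Cluster 6, which held most of the class in YFP+ mutants, held 5.34% and 29.0% of their cells and 0.02% and 0.08% of YFP+ control cells, so that different clusters stood for hepatocytes by genotype. Without YFP+ mutant replicate 2, 2 genes were called.

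**Figure D2:**
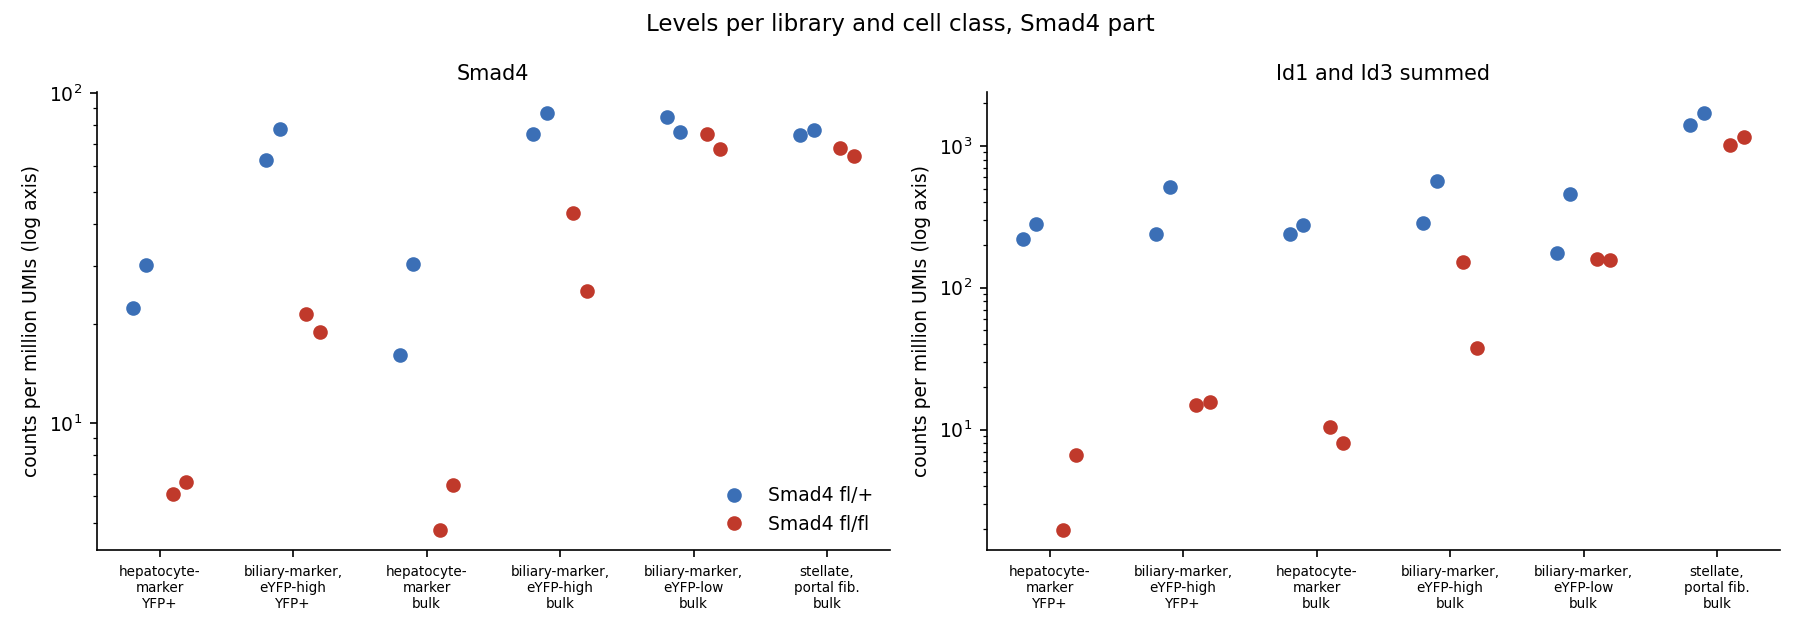
Smad4 (left) and Id1 plus Id3 (right) in CPM of summed UMIs, on log axes, by cell class and sort in the Smad4 part, with 1 point per control (blue) or mutant (red) library. Id1 plus Id3 lies at 219 to 282 CPM in hepatocyte clusters of YFP+ controls and at 1.97 to 6.67 CPM in those of YFP+ mutants.

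In the biliary-cluster cells of mutant YFP+ libraries, 11 cell cycle genes rose, and the BMP targets Id1 and Id3 and 3 TGF-beta targets fell. These changes set cluster 8, which held most of the class in controls, against clusters 3 and 4 in mutants. Ccnb1 (cyclin B1) rose from 6.58 ± 0.504 to 35.2 ± 14.9 CPM, Cdc20 from 10.2 ± 1.63 to 53.4 ± 6.28 CPM and Ccna2 (cyclin A2) from 5.07 ± 0.104 to 32.1 ± 9.44 CPM (SD, n = 2). Id3 fell from 166 ± 95.8 to 4.596 ± 2.40 CPM and Id1 from 232 ± 135 to 14.1 ± 0.102 CPM. Among TGF-beta targets, the matrix protein gene Ltbp2 fell from 35.0 ± 5.48 to 3.31 ± 0.337 CPM. Cdkn1a, which encodes the cell cycle inhibitor p21, fell from 325 ± 36.4 to 120 ± 8.86 CPM, and the receptor gene Tgfbr1 from 68.4 ± 2.68 to 29.3 ± 3.10 CPM. Serpina6 rose from 4.13 ± 1.76 to 111 ± 25.3 CPM, the mucosal peptide gene Tff2 from 8.57 ± 2.49 to 70.0 ± 22.7 CPM and Wfdc18 from 187 ± 75.9 to 1149 ± 72.5 CPM.

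In these clusters 168 of 14229 genes rose and 41 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 19 cell cycle genes rose adjusted over the list alone and 11 over all genes (median log2 fold change 2.00, camera adjusted p = 3.14e-43, adjusted p = 0.0977 with an estimated correlation), with Ccnb1 at 2.43 (SE 0.30, adjusted p = 0.0231) and Cenpf at 2.25 (SE 0.35, adjusted p = 0.0366). Of 10 BMP targets, 5 fell, and 6 fell adjusted over the list alone (median −3.45, camera adjusted p = 1.57e-13, adjusted p = 0.0977 with an estimated correlation). Hamp is among the 5, but its UMIs here need not come from biliary cells. Stellate and portal fibroblast clusters held 419 CPM of Hamp in bulk controls and 1.33 CPM in bulk mutants, and 888 and 0 CPM in 1 YFP+ library of each. Of 21 TGF-beta targets, 3 fell, and 5 fell adjusted over the list alone (median −0.42, camera adjusted p = 6.59e-06, adjusted p = 0.349 with an estimated correlation). Of the biliary markers, which also named the clusters, Cftr and Cd24a rose, while adjusted over the list alone 4 rose and 1 fell (median 0.84, camera adjusted p = 0.000583, adjusted p = 0.349 with an estimated correlation). Fatty acid oxidation genes had a median of −0.51 (camera adjusted p = 0.000583, adjusted p = 0.349 with an estimated correlation). Among mesenchymal genes Fstl1 rose (7.90 ± 0.351 to 36.8 ± 2.89 CPM), adjusted over the list alone 4 rose and 2 fell, and the list as a whole did not pass (median −0.11, camera direction higher). Without cluster 8, 0 genes were called, the median of the cell cycle genes turned to −0.16, and the fold changes of Ccnb1 and Cenpf turned to −0.08 and −0.16. The count was 0 without YFP+ control replicate 1 or replicate 2, 5 without mutant replicate 1, 76 without mutant replicate 2, 31 in eYFP-high clusters alone, 106 with the 4 YFP+ libraries fitted alone and 710 by DESeq2.

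In bulk libraries, where cells that never expressed Cre are included, Serpina6 was the gene that passed: it rose from 9.25 ± 1.80 to 134 ± 23.5 CPM (SD, n = 2). Its log2 fold change was 3.85 (SE 0.28, adjusted p = 0.0441 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), higher in both replicate numbers, and no gene was called without any 1 of the 4 bulk libraries. The BMP targets had a median of −2.01, with 0 of 11 called over all genes and 7 lower adjusted over the list alone (camera adjusted p = 5.79e-16, adjusted p = 0.127 with an estimated correlation). Cell cycle genes had a median of 1.32 (camera adjusted p = 2.69e-19), biliary markers one of 0.68 (camera adjusted p = 3.92e-05) and hepatocyte markers one of −0.85 (camera adjusted p = 1.5e-05), with 0 called adjusted over the list alone and an adjusted p = 0.441 with an estimated correlation for each. Alb stood at −0.89, Apoa2 at −0.73, Spp1 at 0.78 and Epcam at 0.39 on the log2 scale, none past the test. Sums over all bulk cells likewise mix the makeup of a library with levels within a class. Macrophage markers (median −0.61, camera adjusted p = 0.000327) and endothelial markers (median −0.72, camera adjusted p = 0.00224) lay lower in bulk mutants, both with an adjusted p = 0.441 with an estimated correlation. DESeq2 called 41 genes, and 729 of 16050 had an unadjusted p under 0.05.

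In the biliary clusters of bulk libraries, most of whose cells were in cluster 0, Spp1 stood at 0.30, Tm4sf4 at 0.28 and Epcam at −0.38 on the log2 scale, none past the test. Cell cycle genes had a median of 0.90, with 0 called over all genes and 10 higher adjusted over the list alone (camera adjusted p = 8.32e-27, adjusted p = 0.224 with an estimated correlation). BMP targets had a median of −1.06, with 3 lower adjusted over the list alone (camera adjusted p = 3.73e-10, adjusted p = 0.224 with an estimated correlation). All 17 cholesterol synthesis genes had negative fold changes (median −0.67, camera adjusted p = 1.02e-12, adjusted p = 0.678 with an estimated correlation). The TGF-beta targets, with Fn1 at 0.16, Junb at 0.04 and Ctgf at −0.10, had a median of −0.23 (camera adjusted p = 0.00944, adjusted p = 0.678 with an estimated correlation), which was −0.06 without bulk mutant replicate 2. By edgeR's quasi-likelihood test 0 of 14229 genes were called (1 without bulk mutant replicate 1), with 757 at an unadjusted p under 0.05 and 65 by DESeq2.

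Whether the genotype difference itself differed between sorts was tested as an interaction. Markers of non-epithelial cells had the largest medians, at 4.47 for erythroid, 2.55 for mesothelial, 1.84 for stellate and 1.66 for portal fibroblast markers, positive where the mutant-to-control ratio was higher in YFP+ than in bulk libraries. These medians rest on few such cells. Each YFP+ library held 0 to 2 mesothelial, 0 to 5 portal fibroblast and 4 to 31 stellate cells. Haemoglobin made up 0.01% or less of the UMIs of each library. The biliary markers had a median of 0.23, with Spp1 at 0.23, Sox4 at 0.23 and Tm4sf4 at −0.17, and the hepatocyte genes Alb at −0.05 and Apoa1 at −0.49. The TGF-beta targets Fn1, Junb and Cdkn1a stood at −0.35, −0.29 and −0.29. Adjusted over the list alone, 4 mesothelial markers and 3 biliary markers were higher and 2 BMP targets lower. Camera with the preset correlation called 13 lists, each with an adjusted p between 0.408 and 0.833 with an estimated correlation. The edgeR quasi-likelihood test called 0 of 16050 genes, with 465 at an unadjusted p under 0.05 and 67 called by DESeq2, and Smad4 stood at −1.06 (SE 0.42, adjusted p = 1.0).

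The comparison of sorts in Smad4-competent livers asks what sets hepatocyte-derived cells apart from the mixture. Mesenchymal and biliary transcripts were depleted and hepatocyte transcripts enriched in YFP+ libraries. The collagen gene Col1a1 fell from 74.8 ± 51.8 CPM in bulk to 1.01 ± 0.831 CPM in YFP+ libraries, the matrix protein gene Mgp from 316 ± 361 to 4.11 ± 6.15 CPM, and the biliary keratin gene Krt19 from 241 ± 151 to 14.8 ± 9.58 CPM (SD, n = 5). Spink1, a trypsin inhibitor gene, rose from 105 ± 74.3 to 256 ± 68.3 CPM, Igfbp1 from 69.2 ± 27.1 to 174 ± 73.3 CPM and Cps1, the entry enzyme of the urea cycle, from 328 ± 142 to 670 ± 109 CPM. The neutrophil chemokine gene Cxcl5 fell from 233 ± 165 to 15.2 ± 9.96 CPM.

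With week or control group as a stratum, 1242 of 15132 genes were higher and 2388 lower in YFP+ libraries by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By that test, adjusted over all genes, the log2 fold change was −6.46 for Col1a1 (SE 0.64, adjusted p = 0.00045), −4.10 for Krt19 (SE 0.39, adjusted p = 0.000365) and 1.44 for Spink1 (SE 0.37, adjusted p = 0.0219), each in the same direction in 5 of 5 pairs. All 10 portal fibroblast markers fell, also adjusted over the list alone (median −5.63, camera adjusted p = 2.49e-12, adjusted p = 0.214 with an estimated correlation). Of 15 biliary markers, 9 fell, and 9 fell adjusted over the list alone (median −1.10, camera adjusted p = 3.38e-08, adjusted p = 0.214 with an estimated correlation). Of 20 hepatocyte markers, 11 rose, and 17 rose adjusted over the list alone (median 0.84, camera adjusted p = 3.33e-07, adjusted p = 0.299 with an estimated correlation). Macrophage markers such as Marco (8.36 ± 3.67 to 2.11 ± 2.37 CPM) and Clec4f (6.32 ± 1.76 to 1.62 ± 1.20 CPM) fell in 10 of 11 cases and in all 11 adjusted over the list alone (median −1.51, camera adjusted p = 5.12e-07, adjusted p = 0.299 with an estimated correlation), so that transcripts of macrophages were present in the bulk sort. Bile acid genes were higher (7 of those measured, 9 adjusted over the list alone, median 0.73, camera adjusted p = 1.12e-05, adjusted p = 0.214 with an estimated correlation), among them the canalicular transporter gene Abcc2 (76.9 ± 41.8 to 177 ± 83.5 CPM). Smad4 did not differ past the test (0.24, SE 0.20, adjusted p = 0.405). The count was 1913 without week 4, 2104 without the control group and 2415 without week 2.

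In biliary clusters, the duct genes Krt19 and Epcam were lower in YFP+ libraries, while some hepatocyte transcripts and the mesenchymal genes Vim and Cdh2 were higher. Both the lower and the higher levels compare different clusters in each sort. Reporter transcripts (eYFP) rose from 126 ± 78.6 CPM in bulk to 521 ± 171 CPM in YFP+ libraries (SD, n = 5). The surface protein genes Msln and Muc1 fell from 86.2 ± 48.5 to 7.30 ± 8.10 CPM and from 111 ± 34.7 to 8.48 ± 6.74 CPM, the integrin gene Itgb6 from 42.5 ± 19.3 to 2.81 ± 0.436 CPM and the matrix protease gene Mmp7 from 672 ± 231 to 61.7 ± 47.8 CPM. The liver secretory genes Ahsg, Fgb and Hpx rose from 1335 ± 793 to 4174 ± 896 CPM, from 758 ± 365 to 2195 ± 610 CPM and from 1092 ± 539 to 3358 ± 1210 CPM. Part of this may be hepatocyte RNA from outside the counted cells. In stellate and portal fibroblast clusters Ahsg stood at 399 to 961 CPM in 5 bulk libraries and 1710 CPM in the 1 YFP+ library with enough such cells, Fgb at 133 to 801 and 922 CPM, and Hpx at 408 to 1310 and 1980 CPM. Vim (vimentin) rose from 81.4 ± 32.3 to 252 ± 116 CPM and Cdh2 (N-cadherin) from 34.1 ± 17.8 to 96.1 ± 38.4 CPM.

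Of 12952 genes in these clusters, 1143 were higher and 1284 lower in YFP+ libraries by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By that test the log2 fold change was −4.11 for Itgb6 (SE 0.21, adjusted p = 2.37e-05), −4.03 for Muc1 (SE 0.31, adjusted p = 5.98e-05), 1.55 for Vim (SE 0.25, adjusted p = 0.00256) and 2.13 for eYFP (SE 0.54, adjusted p = 0.0198), in the same direction in 5 of 5 pairs. Of the biliary markers, which also named the clusters, 9 fell, such as Krt19 (806 ± 253 to 96.9 ± 49.3 CPM) and Epcam (1327 ± 286 to 310 ± 68.7 CPM), while 9 fell and 1 rose adjusted over the list alone (median −1.12, camera adjusted p = 2.08e-07, adjusted p = 0.149 with an estimated correlation). Of 20 hepatocyte markers, 10 rose, and 11 rose adjusted over the list alone (median 0.88, camera adjusted p = 3.46e-07, adjusted p = 0.197 with an estimated correlation). Chemokine and NF-kappaB genes included 7 that fell, such as Cxcl5 (742 ± 315 to 91.2 ± 52.8 CPM) and Cxcl2 (173 ± 86.4 to 39.2 ± 21.2 CPM), with a median of −0.51 (camera adjusted p = 1.04e-05, adjusted p = 0.197 with an estimated correlation). Antioxidant targets of NRF2 included 6 that rose, 7 adjusted over the list alone, such as Gclc (56.4 ± 10.0 to 107 ± 20.7 CPM), with a median of 0.71 (camera adjusted p = 0.000605, adjusted p = 0.197 with an estimated correlation). Mesenchymal genes went both ways, with 7 higher and 5 lower, also adjusted over the list alone (median −0.08, mean 0.02, camera adjusted p = 0.355). The Notch pathway genes Notch1 (4.36 ± 1.47 to 8.21 ± 1.62 CPM), Notch2 and Jag1 rose, while adjusted over the list alone 3 rose and 3 fell. Macrophage markers fell in 4 cases and in 6 adjusted over the list alone (median −1.03, camera adjusted p = 0.00243, adjusted p = 0.197 with an estimated correlation). Different clusters held the class in each sort, cluster 0 in bulk and cluster 8 in YFP+ controls. In the time course it was cluster 6 in YFP+ libraries and cluster 4 in bulk, except that at week 6 cluster 6 held 370 and cluster 4 held 364 of 748 bulk cells. Without clusters 6 and 8, 622 genes were called (376 higher and 246 lower) and in eYFP-low clusters alone 1. In eYFP-high clusters alone 3 genes were higher and 102 lower, 51 of these 105 with the same call as in all biliary clusters, and Vim, Cdh2, Ahsg, Fgb and Hpx did not pass. In the time course the eYFP-high clusters were 6 and 13. Cluster 13 held 107 of 495, 124 of 394 and 14 of 384 of these cells in bulk at weeks 2, 4 and 6. In YFP+ libraries it held 12 of 276, 20 of 644 and 6 of 510, so this comparison also mixes clusters. The count was 1207 without the control group and 1356 without week 4.

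**Figure D3:**
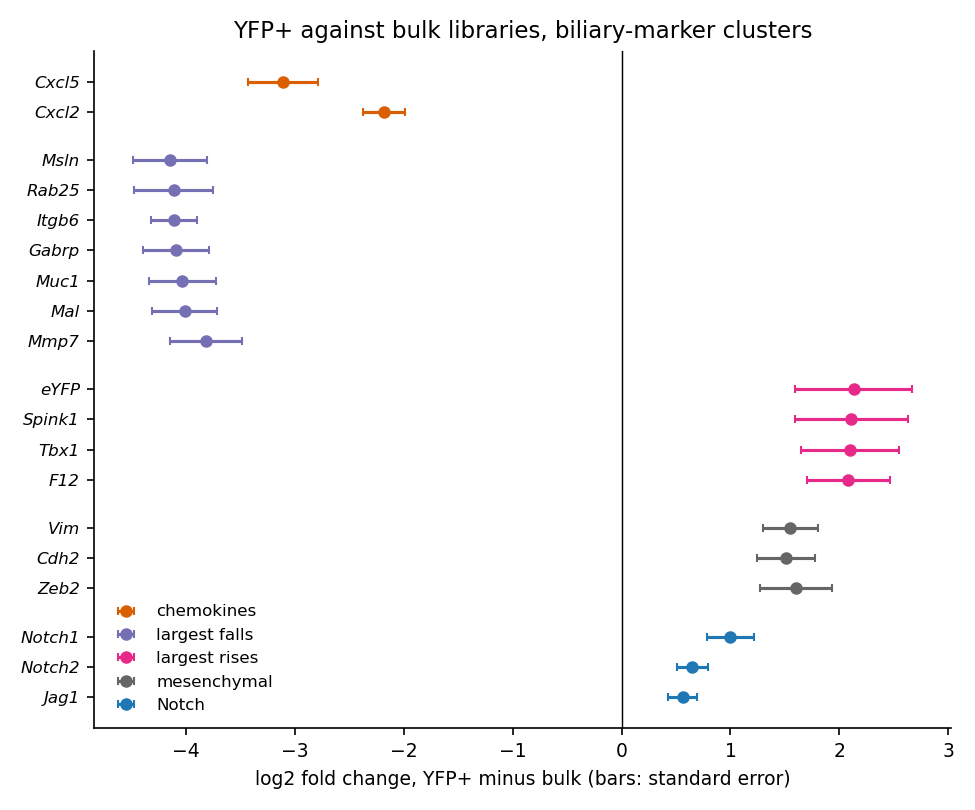
Log2 fold change of YFP+ over bulk libraries in biliary-marker clusters of Smad4-competent livers for 19 of the named genes, coloured by group, with standard errors of the fit as bars. Itgb6 lies at −4.11 and eYFP at 2.13.

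In hepatocyte-cluster cells 11 genes differed between sorts, all lower in YFP+ libraries, among them the biliary keratin gene Krt19 and the collagen gene Col1a1. Of 100 splits of the 10 libraries into 5 and 5, 6 gave as many genes, and of the 24 that part every week and the control group equally, the real one alone did. Krt19 fell from 10.9 ± 9.18 to 0.329 ± 0.21 CPM and Col1a1 from 3.07 ± 2.06 to 0.103 ± 0.0693 CPM in YFP+ libraries (SD, n = 5). Stellate markers had a median of −3.48 (7 of 9 lower adjusted over the list alone, camera adjusted p = 5.65e-14, adjusted p = 0.0705 with an estimated correlation). Macrophage markers had a median of −2.07 (8 of 10 lower adjusted over the list alone, camera adjusted p = 6.92e-25, adjusted p = 0.0705 with an estimated correlation). Part of these differences may be RNA from outside the counted cells, which was not tested. Stellate-like and eYFP-low biliary cells held a larger share of each bulk library than of its YFP+ counterpart. All 11 called genes of 13017 were lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with Krt19 at −4.75 (SE 0.61, adjusted p = 0.0198) and Col1a1 at −5.34 (SE 0.61, adjusted p = 0.0136). The count was 84 by DESeq2, 1 without week 2, 0 without week 4 and 114 (12 higher) without the control group. It was 142 (18 higher) and 72 without control replicate pairs 1 and 2.

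In the time course, Ces3a and Car3 stood higher and Hamp2 lower at week 6 than at week 2 of diet in both sorts. Each week and sort had 1 library, so that these ratios describe libraries, have no replicate check and were not tested. Intervals are exact binomial or Poisson 95% intervals and cover counting error only. The carboxylesterase gene Ces3a stood at 4.3 CPM at week 2 and 328 CPM at week 6 in bulk libraries (log2 ratio 6.25, 5.98 to 6.54) and at 8.63 and 260 CPM in YFP+ libraries (4.91, 4.62 to 5.22). Car3, a carbonic anhydrase gene of pericentral hepatocytes, stood at 74.5 and 568 CPM in bulk and at 64.4 and 592 CPM in YFP+ libraries. Hamp2 went from 927 to 9.79 CPM in bulk (log2 ratio −6.56, −6.72 to −6.41) and from 1040 to 17.3 CPM in YFP+ libraries (−5.91, −6.05 to −5.78); its counts are uncertain next to Hamp. Metallothionein Mt1 went from 6100 to 1840 CPM and from 7960 to 1830 CPM, and Hes1, a Notch target, from 337 to 46.5 CPM in YFP+ libraries.

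Gene groups differed between these weeks in both directions. Against 10000 random lists matched on mean expression, pericentral genes had a median log2 ratio of 1.57 in bulk and 0.95 in YFP+ libraries (percentile 100 in both), and periportal genes −0.98 and −0.87 (percentile 0). Cholesterol synthesis genes (1.09 and 0.84), bile acid genes (1.26 and 0.75) and NRF2 targets (0.84 and 0.72) lay at percentile 100 in both sorts. Drug metabolism genes lay at 0.07 and 0.12 (percentiles 72.7 and 81.8), and fatty acid oxidation genes at 0.99 (percentile 100) and 0.08 (percentile 73.4). TGF-beta targets (−1.08 and −0.73), YAP targets (−0.92 and −1.19) and biliary markers (−0.91 and −0.83) lay at percentile 0. So did dissociation stress genes, a sign of handling, at −0.61 and −0.78. Stellate markers lay at −3.23 and −2.85 and endothelial markers at −3.45 and −4.18. In bulk libraries, dendritic and erythroid markers lay at 1.47 each (percentiles 99.7 and 99.8), on 5 and 3 measured genes. A gene entered a list with 10 UMIs over both weeks, and counts under 3 were raised to 3, so these values may rest on few UMIs. All list medians mix the makeup of the libraries with levels within a class. Within hepatocyte or biliary clusters alone, 82 list medians moved by over 1 SD of the random lists and 18 did not. Within hepatocyte clusters alone the TGF-beta targets lay at −1.29 and −1.48, the YAP targets at −1.22 and −2.15 and the dissociation stress genes at −1.15 and −1.66 (percentile 0). At week 2 this class held 674 of 9666 bulk and 976 of 5529 YFP+ cells, without the unnamed cluster 0. From week 2 to week 6 its barcodes under 1% mitochondrial UMIs went from 146 of 674 to 1728 of 3899 in bulk. In YFP+ libraries they went from 65 of 976 to 5622 of 8518, so these ratios need not compare like cells. Biliary clusters held 14.48%, 14.76%, 50.17% and 15.52% of bulk cells at weeks 2, 3, 4 and 6 and 5.59%, 16.17% and 5.77% of YFP+ cells at weeks 2, 4 and 6. Without cluster 6 these shares were 10.47%, 10.17%, 45.64% and 7.84% in bulk and 0.81%, 2.42% and 0.23% in YFP+ libraries. The difference of week 6 from week 2 was 1.04 points in bulk (−0.20 to 2.28) and 0.18 points in YFP+ libraries (−0.59 to 0.95), with intervals that cover counting error within 1 library each. With a mitochondrial limit of 15% it was 2.77 points in bulk (1.43 to 4.11) and 0.92 points in YFP+ libraries (0.10 to 1.74), and among barcodes with at least 1% mitochondrial UMIs it was −10.73 points in bulk.

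**Figure D4:**
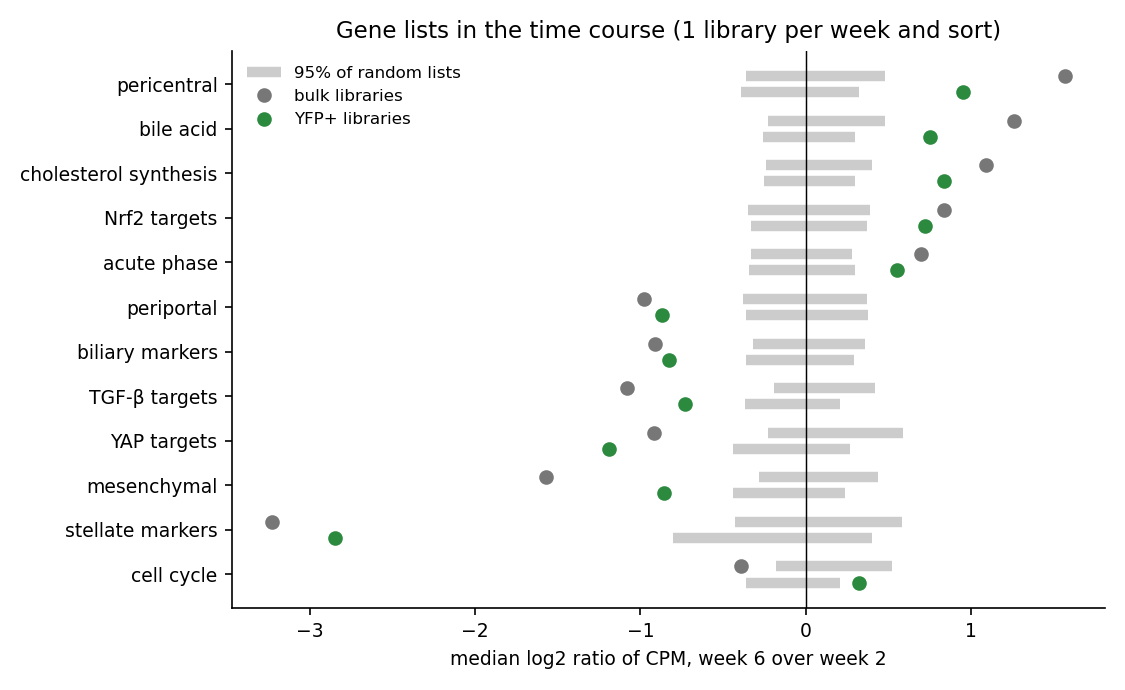
Median log2 ratio of CPM at week 6 over week 2 for 12 gene lists, with 1 bulk (grey) and 1 YFP+ (green) library per week, and grey bars for the range of 95% of matched random lists. The pericentral list lies at 1.57 in bulk and 0.95 in YFP+ libraries, and the periportal list at −0.98 and −0.87.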

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

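Chosen after the result was seen were the tests of native biliary cells, of low-mitochondrial barcodes and of genotype on the biliary share, the test of library makeup on Id1 and Id3, the part of the free RNA test on barcodes of any cluster, and the count over 24 splits; the others were set before.

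Mutant libraries held a larger share of eYFP-high biliary clusters, by a mean of 27.92 percentage points over both sorts. For native biliary cells carried into the YFP+ gate, Smad4 was compared. It stood at 20.1 CPM in these clusters of YFP+ mutants and at 71.2 CPM in the eYFP-low biliary cells of bulk mutants, a ratio of 0.283. These clusters were parted by eYFP, which native cells should lack, so this test could hardly have gone otherwise and decides nothing. The eYFP-low cluster 0 held 1.73% and 3.07% of YFP+ mutant cells and 0.69% and 0.72% of YFP+ control cells. These shares do not measure native cells. In the YFP+ libraries its cells held eYFP at 284 CPM in mutants and 153 CPM in controls, against 30.2 and 15.0 CPM in bulk. Smad4 in its YFP+ mutant cells stood at 40.8 CPM. Barcodes low in mitochondrial UMIs were most frequent in bulk control replicate 1. The difference without them was 29.74 points, or 1.07 times that with them. They made up 1.6% to 8.4% of the YFP+ libraries, too few to move this mean much, so the ratio decides nothing. In bulk libraries the shares were 0.42% and 9.46% in controls and 11.2% and 27.38% in mutants. Without these barcodes they were 1.17% and 11.26% in controls and 15.23% and 33.18% in mutants. Genotype may be the cause, but it cannot be told apart from a chance difference between libraries by the exact test used, whose p of 0.0556 is the smallest that 36 arrangements allow.

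Id1 and Id3 were lower in mutants. A change in the makeup of the libraries is argued against by hepatocyte clusters of YFP+ libraries, where the log2 fold changes were −5.37 and −6.26. The difference was not equal in all cells, with a log2 ratio of Id1 plus Id3 of −4.81 in hepatocyte clusters and −0.52 in stellate and portal fibroblast cells of bulk libraries (1390 to 1710 CPM in controls, 1010 to 1160 CPM in mutants). Loss of Smad4 in the cells that carry the deletion may account for the pattern, but is left open by the eYFP-low biliary cells of bulk libraries, where Smad4 was close to the control level. There the ratio was −1.0, at the limit of 1 from 0 set before, with single pairs of libraries from −1.55 to −0.13.

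Barcodes with under 1% mitochondrial UMIs made up over 50% of several libraries. Nuclei are argued against by nuclear-retained transcripts, which in these barcodes stood at 0.0548 times the level in other hepatocyte-side barcodes (median of 12 libraries, 0.0246 to 0.126). Free RNA in droplets without a cell may be the source and cannot be told apart from cells here, and no biological explanation was tested. In the hepatocyte-side barcodes the ratio of biliary to hepatocyte transcripts was 0.162 times that in mesenchymal and endothelial cells of the same library (median of 8 bulk libraries, 0.035 to 0.37), but choosing barcodes on hepatocyte markers lowers this ratio. Over low-mitochondrial barcodes of any cluster it was 1.21 and 0.427 times in the bulk libraries of weeks 3 and 2, and 0.0411 to 0.226 times in the other bulk libraries.

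The mutant-to-control difference of 13 gene groups differed between sorts by the interaction test with a preset correlation, and none of them with an estimated correlation (adjusted p = 0.408 to 0.833). Their medians (log2, YFP+ minus bulk) were 0.23 for biliary, 1.84 for stellate, 1.66 for portal fibroblast, 0.93 for endothelial, 2.55 for mesothelial and 4.47 for erythroid markers, those of non-epithelial cells resting on few such cells in YFP+ libraries. The medians were −0.32 for BMP targets, 0.42 for mesenchymal genes, 0.70 for cell cycle genes, −0.16 for acute phase genes, −0.29 for dissociation stress genes, −0.25 for endoplasmic reticulum stress genes and 0.58 for basement membrane genes. From week 2 to week 6 the cell cycle genes had a median log2 ratio of −0.39 in bulk and 0.32 in YFP+ libraries, a difference that was not tested.

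Signals appeared in features that no comparison used. Cre transcripts gave 5133 UMIs, with 51 to 1267 in each of the 15 libraries (1.12 CPM in YFP+ mutant replicate 2, the lowest, to 27.5 CPM in the YFP+ library of week 2). The antisense features gave 67 UMIs for Cre and 573 UMIs for eYFP.

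The count of genes that differed between sorts was set against other splits of the 10 libraries into 5 and 5 (100 of 126 splits). For all cells 1 split, the real one, gave as many genes (3630 called, highest other 2134). The fit holds week or control group as a stratum, so that only the 24 splits that part every stratum equally compare with the real one. Of these the highest other gave 1 gene, but 24 splits are too few to exclude chance. For biliary clusters 1 split was as large (2427 called, highest other 1529), and the highest other among those 24 gave 0. For hepatocyte clusters 6 of the 100 splits gave as many as the 11 genes called, while among those 24 the highest other gave 1. The highest of the 100 gave 1819 and has both libraries of weeks 2 and 6 on 1 side and both of week 4 on the other. Within strata it therefore sets bulk control replicate 1 against the other 3 controls, which points to a structure of these libraries whose source was not tested.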

How the results depend on the processing

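Of the alternatives, those on barcodes with at least 1% mitochondrial UMIs, on biliary clusters parted by the leading-gene check or by eYFP, on shares over epithelial clusters and on clustering without genes called by genotype were chosen after the results were seen. Across alternatives, 4431 values of named genes kept their direction and side of the threshold, 732 kept their direction but lost the call, 5 gained it and 27 reversed. For gene lists these numbers were 1891 kept, 189 lost and 11 reversed, and of the counts of called genes 96 stayed within a factor of 1.5 and 59 did not. In the untested time course, 82 list medians moved within hepatocyte or biliary clusters alone and 18 did not. All 20 alternatives of the biliary share difference by genotype kept its direction (27.92 to 45.86 points) and missed the threshold, which the exact test cannot reach with these numbers of libraries. The cause of the changes below was not tested. DESeq2 changed the test and the scaling together, and leaving out libraries or cells leaves fewer to test. Depth limits genes of a few UMIs, and 2 libraries per group limit the genotype tests.

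With DESeq2 the counts were 1061 (YFP+, all cells), 41 (bulk, all cells), 67 (interaction), 32 (YFP+, hepatocyte clusters), 710 (YFP+, biliary clusters), 65 (bulk, biliary clusters) and 84 (sort, hepatocyte clusters). All 73 genes of the YFP+ comparison over all cells and all 209 of its biliary clusters were called again by DESeq2. Without the filter on low counts they were 344 for all YFP+ cells, 23 and 526 for hepatocyte and biliary clusters of YFP+ libraries, 2 for biliary clusters of bulk libraries and 118 for sort in hepatocyte clusters. With doublets kept they were 2, 126 and 17 for YFP+ hepatocyte clusters, YFP+ biliary clusters and sort in hepatocyte clusters. At resolutions of 0.5 and 2, 1 gene was called in each for YFP+ hepatocyte clusters. In bulk libraries over all cells, 0 genes were called with a mitochondrial limit of 15%, with at least 1% mitochondrial UMIs, or with the 4 bulk libraries alone. With the 4 YFP+ libraries alone the counts were 0 for all cells and 106 for biliary clusters, and with YFP+ and bulk counts summed 0. With mutant libraries added, sort in hepatocyte clusters gave 82.

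The labels do not say that equal replicate numbers share a mouse, day or batch, and 2 numbers are too few to show it, so the fits were made without pairing and the exact test treats the sorts as separate. With the replicate block, 230 genes were called for all YFP+ cells, 0 for all bulk cells, 14 and 803 for hepatocyte and biliary clusters of YFP+ libraries and 135 for sort in hepatocyte clusters, and the exact p of the biliary share was 0.125, the smallest that 16 arrangements allow. Deviations of same-numbered libraries correlated between groups with r from 0.04 (bulk control and YFP+ mutant) to 0.59 (bulk mutant and YFP+ mutant). The highest values joined the sorts of a genotype, at 0.59 in mutants and 0.54 in controls. If bulk and YFP+ libraries of a number share mice, they are not independent. The exact p of 0.0556 from 36 arrangements would then be too small, and the spread in the fits would rest on fewer units. With the block, Smad4 passed in YFP+ hepatocyte clusters (log2 fold change −2.08), Serpina6 in bulk libraries did not, nor did the erythroid list in bulk libraries, the periportal list in bulk biliary clusters and the YAP target list for sort in hepatocyte clusters. It changed no other call of a named gene or list and moved no other count of genes by over 1.5 times.

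Leaving out 1 library at a time gave 0 to 495 called genes for all YFP+ cells (highest without YFP+ mutant replicate 2), 0 for all bulk cells, 0 to 2 for YFP+ hepatocyte clusters, 0 to 76 for YFP+ biliary clusters and 0 to 1 for bulk biliary clusters. Leaving out a stratum or control pair gave 1913 to 4706 for sort over all cells, 1207 to 2630 in biliary clusters and 0 to 142 in hepatocyte clusters. The biliary share difference ranged from 29.92 points (without bulk control replicate 1) to 44.84 points. List medians that reversed were stellate markers in bulk libraries (−3.00 to 0.50, highest without bulk control replicate 1) and acute phase genes in the interaction (−1.27 to 0.58, with 0.46 without YFP+ mutant replicate 1). Others were drug metabolism genes (−0.98 to −0.05) and TGF-beta targets (−0.38 to −0.01) in bulk biliary clusters and dissociation stress genes for sort in hepatocyte clusters (−0.07 to 0.41); where a median keeps its sign, the test's direction reversed.

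Without the clusters failing the leading-gene check, 0 genes were called by genotype in YFP+ biliary clusters, mesothelial markers stood at −0.45 and cell cycle genes at −0.16, and Cenpf stood at −0.16, Tpx2 at −0.12, 2810417H13Rik at −0.03 and Ccnb1 at −0.08. For sort in biliary clusters 622 genes were called, 433 of them among the 2427, and Urod stood at −0.03, Sesn2 at −0.18, Hmgb2 at 0.92, Sc5d at −0.04 and Tagln at 0.15. In eYFP-high clusters alone the counts were 31 by genotype in YFP+ libraries and 105 for sort, and basement membrane genes in bulk libraries stood at 0.31. In eYFP-low clusters alone the counts were 0 by genotype in YFP+ libraries and 1 for sort. By genotype in YFP+ libraries, fatty acid oxidation genes then stood at 0.18, Cenpf at −0.16, Tpx2 at −1.07, Cdc20 at −0.58, Cftr at −0.28, Fstl1 at −0.14 and Ier3 at 0.02. For sort, macrophage markers stood at −0.10, Zeb2 at −0.31, Urod at −0.20, Sesn2 at −2.74, C1qb at 0.32, Abcb4 at −0.76, Blvrb at −0.12, Sc5d at −0.02, Tagln at 0.50, Nr1i2 at −0.33, Upk1b at 0.13, Csf1r at 0.15 and Ankrd1 at 0.03. The week 6 minus week 2 difference in biliary share moved to 2.77 points in bulk with a mitochondrial limit of 15%, and to −10.73 points in bulk and −0.67 points in YFP+ libraries with at least 1% mitochondrial UMIs.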

Other observations

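The gene group tests between sorts and the untested ratios of the time course were planned; choosing these groups to describe came after the values were seen.

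Cell cycle genes went different ways in hepatocyte and biliary clusters between weeks 2 and 6 of diet. Within hepatocyte clusters, cell cycle genes had a median log2 ratio of 1.25 in bulk and 1.04 in YFP+ libraries (percentile 100 among matched random lists), while within biliary clusters they had −1.47 and −0.68 (percentile 0). Notch pathway genes within hepatocyte clusters lay at −1.70 and −1.94 and biliary markers at −1.72 and −1.61 (percentile 0). Among hepatocyte-cluster barcodes, those with under 1% mitochondrial UMIs were also more frequent at week 6. They went from 146 of 674 to 1728 of 3899 in bulk and from 65 of 976 to 5622 of 8518 in YFP+ libraries. The list ratios above therefore need not describe intact cells. Over all kept barcodes, the share of such barcodes was lower at week 6 than at week 2 in both sorts. The hepatocyte class leaves out the unnamed cluster 0, which held most cells of week 2. Antioxidant targets of NRF2 lay at 0.82 and 0.96 within hepatocyte clusters (percentile 100). Different clusters held the hepatocyte class, cluster 3 with 5.17% of bulk cells at week 2 and clusters 5 and 8 with 37.7% and 27.58% at week 6. Cluster 6, without a biliary marker among its leading genes, held 388 of 1400 biliary-cluster cells of the bulk library at week 2 and 370 of 748 at week 6. The hepatocyte class held 6.97% of bulk cells at week 2, and 55.13% at a resolution of 2. With 1 library per week and sort, these values describe libraries and were not tested.

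Basement membrane genes differed between sorts in biliary clusters: 8 of 14 were lower and 2 higher in YFP+ libraries, also adjusted over the list alone (median −0.55, camera adjusted p = 9.18e-06, adjusted p = 0.197 with an estimated correlation). Lamb3, a laminin chain, fell from 37.8 ± 16.2 to 4.52 ± 1.94 CPM (SD, n = 5). Fatty acid oxidation genes were higher in 6 of 12 cases and in 7 adjusted over the list alone (median 0.71, camera adjusted p = 0.000358, adjusted p = 0.197 with an estimated correlation). Different clusters held the biliary class in each sort. In eYFP-high clusters alone 3 genes of any kind were higher, fewer than these 6, and 51 of the 105 genes called had the same call as in all biliary clusters. Among YAP targets, 3 fell, also adjusted over the list alone, such as Ankrd1 (355 ± 136 to 150 ± 100 CPM), and the list did not pass (median −0.09, camera adjusted p = 0.102).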
